A study of Mus musculus with 10 samples.

How the data were processed

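Total RNA from the cochlea of male CBA mice, 5 samples after GeO2 in the diet and 5 on normal chow, was amplified to biotin-labelled cRNA and hybridised to Affymetrix arrays, 1 array per sample, per the labels' protocols. The deposited values are linear intensities, 1 signal per probe set and array, made with GCOS (Affymetrix) version 1.3 per the submitters' processing notes. No value was at or below 0. The 2% trimmed mean was 1496 on each array, so the authors' values had already been scaled between arrays; the target of that scaling is not given in the sources used here. The value table holds 45037 probe sets and 10 arrays, and no column of values was left unused. Control probe sets were not analysed here, so no ratio of 3' to 5' signal was computed as a measure of RNA quality.

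The authors' deposited table of significant genes gives, per its header and closing note, a p-value and a signed fold change (a score with a minus sign where GeO2 is lower) for 7806 probe sets, with gene symbols and Gene Ontology categories. The test behind the p-values is not named there. All 7806 deposited p-values lay within 1e-05 of a pooled-variance test of 2 samples on the linear intensities, and all 7806 signs went with the ratio of group means. That test gave 9437 probe sets at a p under 0.05, of which 1631 are outside the authors' table, 1346 of these with a ratio of means of at least 1.2, so the table rests on a further selection that its note does not state. The note prints its thresholds with the inequalities the wrong way round for the values it accompanies. After Benjamini-Hochberg adjustment over all 45037 probe sets, the same test gave 2235.

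For the present work, log2(signal + 16) was taken of the intensities as deposited, with no further scaling. Probe sets whose mean log2 value over all 10 arrays lay in the lowest 40% were left out (18015), which left 27022. Differences are GeO2 minus control on this scale, which understates the change of dim probe sets. Fold values are powers of 2 of these differences, not ratios of mean signals. limma 3.58.1 in R 4.3.3 was fitted with lmFit and eBayes with a mean-variance trend, two-sided, and p-values were Benjamini-Hochberg adjusted over the 27022 probe sets, with a threshold of 0.05. The smallest absolute log2 change called was 0.204 and the median standard error was 0.17. The same code was tested on simulated data with 200 changed probe sets of 27022, where it made 4 false calls, and on simulated lists, where the shifted list and 1 other of 28 were called. The simulated probe sets varied independently of each other, so the simulated lists do not test the list calls under correlation between genes.

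Probe sets were named only from the authors' deposited table, where 7095 had 1 symbol, 87 several and 611 none, and 13 symbols had been turned into a date or a number. The 37231 probe sets outside that table are unnamed here. Old symbols were updated through a table of mouse RefSeq genes on GRCm38.p6, used for names only: 4291 symbols were current, 2357 matched a synonym, 31 were a synonym of several genes and 416 had no match and were kept as listed. Where a RefSeq accession stood beside the symbol (1176 probe sets), 1171 gave the same gene and 5 were named from the accession. No genome build is given in the sources used here, and no coordinates are reported.

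Before the data were examined, 46 gene lists (mitochondrial and energy pathways, stress and repair responses, cochlear cell types, and neighbouring or blood-derived cell types) and the rule for named genes were fixed. By that rule, the text names, among probe sets with 1 symbol that passed the threshold and were separated in all 25 pairwise comparisons, the 12 with the largest rise and the 12 with the largest fall, 1 per gene at the highest mean. It also names up to 4 members of each list described, by largest change among those that passed or else by smallest p, and 14 genes fixed in name. Some genes that the rule selects are not reported here. Others named in the closing section or as further list members were chosen after their values were seen. Lists with at least 5 members measured (28 of 46) were tested with limma's camera, preset correlation 0.01, over 5115 genes, with Benjamini-Hochberg adjustment over the 28 lists. Each gene had 1 probe set, the one with the highest mean among those tested and named in the authors' deposited table. A list member counts as measured only if it has such a probe set. Because names come from the authors' table, camera compared each list with other genes of that table, and list members outside it were not analysed here; the same holds for the Gene Ontology test, a one-sided Fisher's exact test over categories of at least 10 genes. Both therefore ran on genes selected on these arrays. List scores are the mean log2 value of the members on an array.

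The alternatives tried were quantile normalization, a shift of each array to 1 median, offsets of 1 and 64, no filter and a 60% filter, each array left out in turn, the replicate number as a block, array weights, no trend and a robust trend, an adjusted p under 0.10, an exact rank-sum test, a minimum fold of 1.5, estimated correlations and fry in place of camera with its preset, and the mean of all probe sets of a gene. A pooled-variance test on linear signals and the erythroid score as a covariate were added after seeing the data. Groups were taken from the sample labels, and exact permutation tests rearranged arrays within groups for correlations (all arrangements) and between groups for single differences. Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for tables and plots.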

Results

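Transcript levels were measured in cochlear RNA from 10 samples of male CBA mice, an inbred strain widely used in hearing research, all 6 months old. Germanium dioxide (GeO2), an oxide of germanium whose long-term intake is known to injure kidney, muscle and nerve, was given in the diet at 0.15% for 4 months to the group of 5 samples called GeO2 here. The other 5 samples, called control, came from mice on normal chow. Each sample was hybridised to 1 Affymetrix array holding 45037 probe sets. Median signal ran from 447 to 508 units between arrays and the trimmed mean was 1496 on each. The number of arrays limits the precision. The labels do not say whether each sample is 1 animal or a pool, and the series' design notes say that replicates were not done while counting 5 samples per group. The p-values measure only the spread between these samples, which may be technical in part or in whole.

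The comparison of GeO2 with control asks which cochlear transcripts differ in mice with hearing loss related to GeO2. Transcripts of red cell precursors and of dividing cells, a strial potassium channel subunit and the antioxidant enzyme glutathione peroxidase 1 were lower in GeO2, and transcripts of the innate immune protein Lcn2 and of the stress-induced genes Gdf15 and Trib3 were higher. Dnase1, a secreted endonuclease, fell from 42182 ± 2915 to 5154 ± 2519 signal units (SD, n = 5), which is 9.05-fold lower. Kcne1, the subunit that joins Kcnq1 in the potassium channel of strial marginal cells, fell from 2206 ± 605 to 346.9 ± 257 units (SD, n = 5), or 7.76-fold. Lcn2, the siderophore-binding lipocalin, rose from 795.4 ± 461 to 11774 ± 10146 units (SD, n = 5), a 12.1-fold difference in the mean of log2 values. Gdf15, a secreted factor induced in mitochondrial and integrated stress responses, rose 3.93-fold from 269.6 ± 102 to 1069 ± 248 units (SD, n = 5). In total, 4408 of the 27022 probe sets tested changed (16.3%), 2297 higher and 2111 lower in GeO2, at a Benjamini-Hochberg adjusted p under 0.05 in limma. Of these, 191 were higher and 427 lower by at least 2-fold, and 12 were higher and 64 lower by at least 4-fold. The count fell to 2794 without GeO2 replicate 5 and to 2815 without control replicate 1. On simulated data of the same size in which 200 probe sets were changed, far fewer than were called here and so with a stricter adjustment, the fit recovered 16.7% of 1.5-fold changes, 65.6% of 2-fold changes and 95.3% of 3-fold changes.

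Among genes past the test and separated in all 25 pairwise comparisons, the 12 with the largest falls included genes of red cell precursors or their membranes. Trim10 changed by −3.14 (SE 0.52), Rhd, listed as Rhced, by −3.09 (SE 0.44) and Klf1, the erythroid transcription factor, by −3.01 (SE 0.37) on the log2 scale. Cldn13 (−2.74, SE 0.44), Eraf, the chaperone of alpha haemoglobin (−2.69, SE 0.38), and Nfe2 (−2.63, SE 0.43) fell as well. Apol11b, listed as A330102K04Rik, changed by −3.15 (SE 0.48), and the proliferation genes Ube2c and Tk1 by −2.62 (SE 0.41) and −2.59 (SE 0.47). The 12 largest rises held, besides Lcn2 and Gdf15, the myeloid receptor genes Clec4n (1.97, SE 0.44) and Msr1 (1.51, SE 0.37). They also held Nfkbiz, an inducible regulator of NF-kappaB target genes (1.46, SE 0.24), Trib3, a pseudokinase induced by ATF4 (1.43, SE 0.16), and Ncl, nucleolin (1.40, SE 0.20), whose brighter probe set, not separated in all comparisons, rose by only 0.36. Kns2 (1.77, SE 0.36), Gtf2i (1.61, SE 0.20), Gmfb (1.61, SE 0.37), 8430436C05Rik (1.55, SE 0.17) and Slc5a3, listed as BF642829 (1.41, SE 0.31), made up the rest. Adjusted p-values of the 24 genes with the largest rises and falls ran from 0.000152 for Dnase1 to 0.0154 for Msr1, and all 24 stayed under 0.05 whichever single array was left out.

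**Figure D1:**
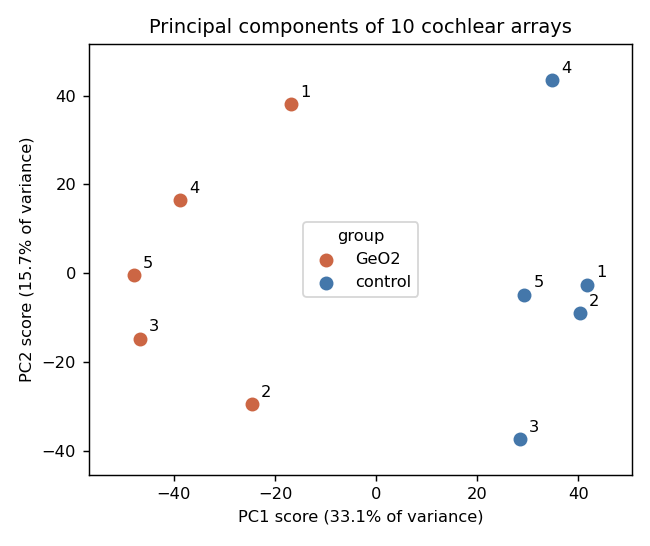
Scores of the 10 arrays on the first principal component (horizontal axis, 33.1% of the variance) and on the next one (vertical axis, 15.7%), from log2(signal + 16) of the probe sets tested. Points are arrays, numbered by replicate and coloured by group, and the GeO2 arrays all lie at negative scores from −47.87 to −16.81 on the first component while the control arrays lie from 28.49 to 41.73.

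Markers of erythroid cells formed the list with the lowest median change. Of 15 members measured, 14 fell and 1 did not pass, and 15 passed when adjusted over the list alone. Of the 14 falls, 12 passed whichever single array was left out. Epb42, a red cell membrane protein, changed by −3.10 (SE 0.56) and Klf1 by −3.01, with a list median of −2.41. The mean log2 value of the list, the erythroid score, was 10.90 ± 0.90 in GeO2 and 12.95 ± 0.42 in control (SD, n = 5). Hba-a1, alpha globin, was the member that did not pass at its brightest probe set (−0.21, adjusted p = 0.128 in limma). The list stood apart from the other genes tested (camera, adjusted p = 0.000116), but not with a correlation estimated for each list (adjusted p = 0.407 with an estimated correlation). All list members are measured through names that occur only in the authors' deposited table, which was selected on these arrays at an unadjusted p under 0.05. Adjustment over a list of such members alone passes nearly all of them by construction, so those counts, here and below, support no list. The counts per list are not independent evidence of a direction either.

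All 25 measured members of the cell cycle list fell, with a median of −1.52, and 25 passed when adjusted over the list alone; 21 passed whichever single array was left out. Ube2c, which targets mitotic cyclins for destruction, fell most, followed by the mitotic cyclin Ccnb2 (−2.12, SE 0.31), the spindle protein Nusap1 (−2.08, SE 0.39) and the kinase Cdk1 (−2.03, SE 0.36). Camera gave an adjusted p = 6.88e-07, and an adjusted p = 0.407 with an estimated correlation. The erythroid score moved with this list. Within groups, the deviations of both scores from their group means gave a Pearson r of 0.91 (permutation p = 0.00111, adjusted p = 0.01 over 9 lists, 10 arrays) and a Spearman rho of 0.88 (permutation p = 0.00347). Without the 2 arrays farthest from the median erythroid deviation, r was 0.93. With the erythroid score as a covariate, an alternative chosen after seeing the data, the list median was −0.26 and its call was lost (camera, adjusted p = 0.311).

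The measured subunit genes of the respiratory chain and of ATP synthase were mostly lower in GeO2. Over complexes I to V, 47 of 81 listed subunit genes were measured. Of these, 36 fell, 3 rose and 8 did not pass, with a median of −0.55, and 47 passed when adjusted over the combined list alone. Whichever single array was left out, 23 of the 36 falls and 2 of the 3 rises passed. In complex I, NADH dehydrogenase, 19 of 37 listed genes were measured. Of these, 13 fell, 2 rose and 4 did not pass, with 19 passing adjusted over the list alone. Ndufa3 changed by −1.03 (SE 0.12), Ndufab1 by −0.88 (SE 0.15) and Ndufb2 by −0.72 (SE 0.14). In complexes II and III, 10 of 14 listed genes were measured. Of these, 7 fell, none rose, 3 did not pass and 10 passed adjusted over the list alone. Uqcr10 changed by −1.31 (SE 0.28), Uqcrq by −1.06 (SE 0.15) and Uqcrc1 by −0.82 (SE 0.10). In complex V, ATP synthase, 12 of 16 listed genes were measured. Of these, 11 fell, led by Atp5k at −1.49 (SE 0.17) and Atp5a1 at −1.22 (SE 0.23). Atp5c1 rose by 0.90 (SE 0.17), and 12 passed adjusted over the list alone. Camera adjusted p-values were 0.00363 for complex I, 0.0132 for complexes II and III and 0.00335 for complex V, and each became an adjusted p = 0.407 with an estimated correlation. Complex IV, cytochrome c oxidase, had 6 of 14 listed genes measured. Of these, 5 fell and 1 did not pass, with 6 passing adjusted over the list alone. Of the 5 falls, 1 passed whichever single array was left out. The list just missed the threshold (camera, adjusted p = 0.0538; adjusted p = 0.529 with an estimated correlation). It was called without GeO2 replicate 3 (adjusted p = 0.0282), control replicate 1 (0.0404) or control replicate 5 (0.0224), under quantile normalization (0.0378), with the lowest 60% of probe sets left out (0.0472), with the mean of all probe sets of a gene (0.0275), with fry (0.00327), and with the erythroid score as a covariate, chosen after seeing the data (0.00938). Its strongest falls, Cox8b (−1.07, SE 0.29) and Cox7a1 (−0.90, SE 0.23), encode isoforms abundant in muscle. Cox8b lost its call when any of 4 single arrays was left out and Cox7a1 when any of 2 was, with adjusted p up to 0.0652 and 0.054. The erythroid score, lower by 2.05 in the same GeO2 arrays on average, did not track these lists within groups, with r of −0.32 for complex I, −0.37 for complexes II and III and −0.43 for complex V (permutation p = 0.381, 0.347 and 0.408, each 0.558 when adjusted over 9 lists). Spearman's rho was −0.33, −0.14 and −0.03 (permutation p = 0.38, 0.725 and 0.942), and r without the 2 farthest arrays was −0.09, 0.27 and 0.32.

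Of 57 mitochondrial ribosome genes listed, 29 were measured. Of these, 13 fell, 1 rose and 15 did not pass, with 27 passing adjusted over the list alone and a median of −0.38. Of the 13 falls, 6 passed whichever single array was left out, as did the rise. Mrps12 (−0.98, SE 0.14) and Mrpl34 (−0.88, SE 0.19) fell, and Mrpl50 rose by 1.10 (SE 0.17). Camera gave an adjusted p = 0.0126 for this list, and an adjusted p = 0.407 with an estimated correlation. The erythroid score was lower in the same GeO2 arrays, and within groups it gave r of −0.48 with this list (permutation p = 0.312, adjusted p = 0.558 over 9 lists), rho of −0.32 (permutation p = 0.43) and r of 0.38 without the 2 farthest arrays. Among 12 measured tricarboxylic acid cycle genes, of 21 listed, 6 fell, 1 rose and 5 did not pass (camera, adjusted p = 0.234). Idh3g changed by −0.86 (SE 0.09). All 6 falls passed whichever single array was left out, and the rise did not. Glycolysis, with 6 of 19 listed genes measured, had 4 that fell, 1 that rose and 1 that did not pass (camera, adjusted p = 0.204). Fatty acid oxidation, with 7 of 18 listed genes measured, had 3 that fell, 1 that rose and 3 that did not pass (camera, adjusted p = 0.43). Whichever single array was left out, 2 of the 4 glycolysis falls passed, but not the rise, and 0 of the 4 changes in fatty acid oxidation. Of 22 genes listed for mitochondrial biogenesis and DNA maintenance, 11 were measured. Of these, 2 rose, 1 fell and 8 did not pass (camera, adjusted p = 0.708). Nrf1, nuclear respiratory factor 1, rose by 1.39 (SE 0.32), the 1 change of this list that passed whichever single array was left out.

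**Figure D2:**
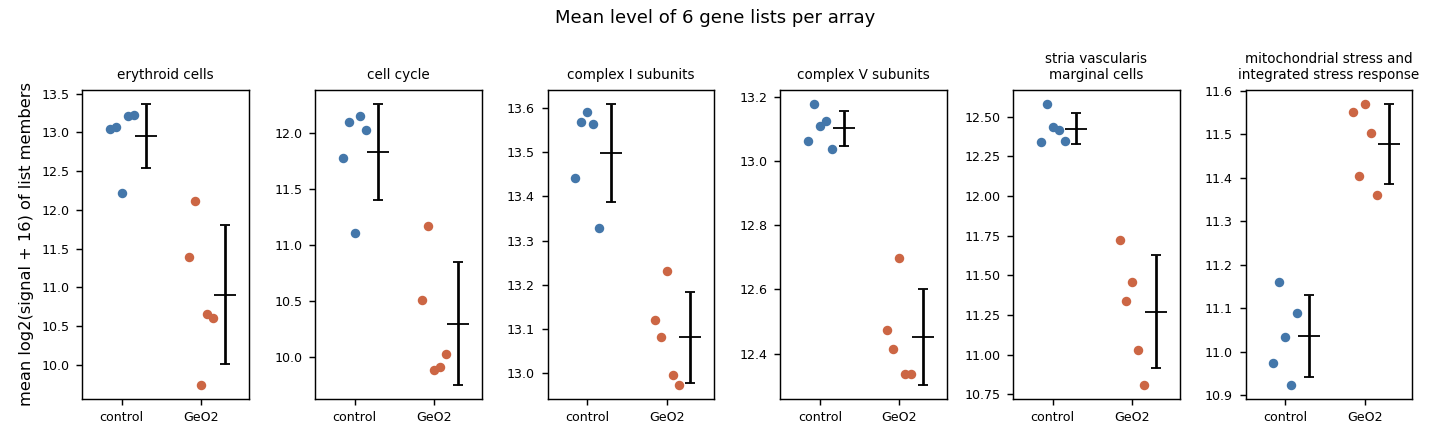
Mean log2(signal + 16) of the members of 6 gene lists (vertical axes, not starting at 0) for control and GeO2. Points are arrays and the bar beside them gives the mean and SD of 5 arrays. All 5 GeO2 arrays lie below all 5 control arrays for the erythroid, complex I, complex V and marginal cell lists and above them for the stress response list, while for the cell cycle list GeO2 replicate 2 (11.16) lies above control replicate 3 (11.10). The control arrays hold 1 low erythroid value of 12.22 in replicate 3.

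The measured genes of the mitochondrial stress and integrated stress response rose more often than they fell. Of 22 genes listed, 14 were measured. Of these, 5 rose, 2 fell and 7 did not pass, with a median of 0.43 and 14 passing adjusted over the list alone. Gdf15 and Trib3 rose by 1.98 and 1.43, the mitochondrial chaperone gene Hspa9 by 0.83 (SE 0.12), and the mitochondrial protease genes Lonp1 and Clpx by 0.57 and 0.51. Hspe1, the mitochondrial chaperonin cofactor, fell by 0.64 (SE 0.17), with its call lost when any of 5 single arrays was left out (adjusted p up to 0.0666), and Shmt2 changed by −0.52. All 5 rises passed whichever single array was left out, and neither fall did. Camera gave an adjusted p = 0.0498, just under the threshold, and an adjusted p = 0.407 with an estimated correlation. The call was lost without GeO2 replicate 1 (adjusted p = 0.0656), GeO2 replicate 3 (0.0695), control replicate 1 (0.0506), control replicate 3 (0.0539) or control replicate 4 (0.0653), with the replicate number as a block (0.054), with an offset of 1 (0.0503), with array weights (0.0756), with the lowest 60% of probe sets left out (0.13), and with the erythroid score as a covariate, chosen after seeing the data (0.113). The erythroid score was lower in the same GeO2 arrays, and within groups it gave r of −0.26 with this list (permutation p = 0.496, adjusted p = 0.558 over 9 lists), rho of −0.05 (permutation p = 0.886) and r of 0.24 without the 2 farthest arrays.

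The measured antioxidant and NRF2 target genes were mostly lower. Of 29 genes listed, 17 were measured. Of these, 10 fell, 1 rose and 6 did not pass, with a median of −0.52 and 17 passing adjusted over the list alone. Of the 10 falls, 7 passed whichever single array was left out, as did the rise. Gpx1, glutathione peroxidase 1, fell from 34125 ± 5648 to 8466 ± 2017 units (SD, n = 5), a log2 change of −2.03 (SE 0.17, adjusted p = 0.000129 in limma). Ucp2, a mitochondrial carrier, changed by −1.21 (SE 0.21) and Txnrd2, mitochondrial thioredoxin reductase, by −0.80 (SE 0.18), while Gsr, glutathione reductase, rose by 0.95 (SE 0.18). The superoxide dismutase genes Sod1 (−0.47, SE 0.13) and Sod2 (−0.41, SE 0.12) fell with all arrays, but each lost its call when any of 6 single arrays was left out (adjusted p up to 0.0778 and 0.0804). Camera gave an adjusted p = 0.00916 for the list, and an adjusted p = 0.407 with an estimated correlation. Within groups, the list and the erythroid score gave a Pearson r of 0.69 (permutation p = 0.109, adjusted p = 0.488 over 9 lists), a Spearman rho of 0.79 (permutation p = 0.0392) and r of 0.78 without the 2 farthest arrays. Gpx1, like the erythroid score, was lowest among controls in replicate 3 and highest among GeO2 arrays in replicate 2. Loss of erythroid precursors was not weighed as a cause for Gpx1 or this list and stays open.

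In RNA from the cochlea, measured markers of strial marginal cells and of spiral ligament fibrocytes and the limbus were lower in GeO2. These parts were not measured apart from the rest of the cochlea. Strial marginal cells secrete potassium into the endolymph. All 6 of their measured marker genes, of 13 listed, fell, with a median of −0.83 and 6 passing adjusted over the list alone. Kcne1 fell at both of its probe sets (−2.96, SE 0.46, and −3.88), Kcnq1 by 1.24 (SE 0.28) and the sodium pump subunit gene Atp1b2 by 0.99 (SE 0.13). The sodium-potassium-chloride cotransporter gene Slc12a2 fell by 0.56 (SE 0.14), with its call lost without GeO2 replicate 5 (adjusted p = 0.0547), and Esrrb by 0.67 (SE 0.21), with its call lost when any of 8 single arrays was left out (adjusted p up to 0.113). All 7 measured markers of spiral ligament fibrocytes and the limbus, of 18 listed, fell, with a median of −0.64 and 7 passing adjusted over the list alone. They included Kcnk2 (−1.03, SE 0.18), Car3 (−0.92, SE 0.18), Slc4a11 (−0.69, SE 0.14) and Otor (−0.64, SE 0.15). Of the falls, 3 of 6 in marginal cells and 5 of 7 in fibrocytes passed whichever single array was left out. The lists share members, Slc12a2 among them. Camera adjusted p-values were 0.0174 for marginal cells and 0.0126 for fibrocytes, and each became an adjusted p = 0.407 with an estimated correlation. The erythroid score was lower in the same arrays, and within groups it gave r of 0.18 with the marginal cell list and 0.30 with the fibrocyte list (permutation p = 0.758 and 0.48, adjusted 0.758 and 0.558 over 9 lists). Spearman's rho was 0.24 and 0.42 (permutation p = 0.554 and 0.292), and r without the 2 farthest arrays was 0.54 and 0.57.

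Intermediate cells of the stria, which are melanocytes, had only 4 measured markers and were not tested as a list. All 4 fell: Tyr, tyrosinase (−1.06, SE 0.29), Mitf (−0.83, SE 0.19), Dct (−0.49, SE 0.11) and Kit (−0.46, SE 0.13). The erythroid score was lower in the same GeO2 arrays, and its relation within groups was not computed for these genes. Tyr lost its call when any of 5 single arrays was left out (adjusted p up to 0.0573) and Kit when any of 6 was (up to 0.0671). The wider potassium recycling and endolymph list, which shares Kcne1, Kcnq1 and Slc12a2, had 12 of 24 listed genes measured. Of these, 7 fell, 4 of them whichever single array was left out, and 5 did not pass (camera, adjusted p = 0.109). Of 18 supporting cell and tectorial membrane genes listed, 7 were measured. Of these, 4 rose and 3 did not pass, and the list was not called (camera, adjusted p = 0.116). Sox2, a supporting cell transcription factor, rose by 0.91 (SE 0.17) and Fgfr3 by 0.62 (SE 0.15). Otog and Slc1a3 rose by 0.73 and 0.58 with all arrays, but lost their calls when any of 7 and of 4 single arrays was left out, with adjusted p up to 0.101 and 0.0711. Gjb6, connexin 30, was at 0.20 (SE 0.08, adjusted p = 0.116 in limma), which did not pass. Kcnj10, Gjb2, Coch, Slc26a5, Myo7a, Cox4i1 and Ndufs1, also fixed for report beforehand, have no probe set named in the authors' deposited table among those tested and were not analysed here.

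**Figure D3:**
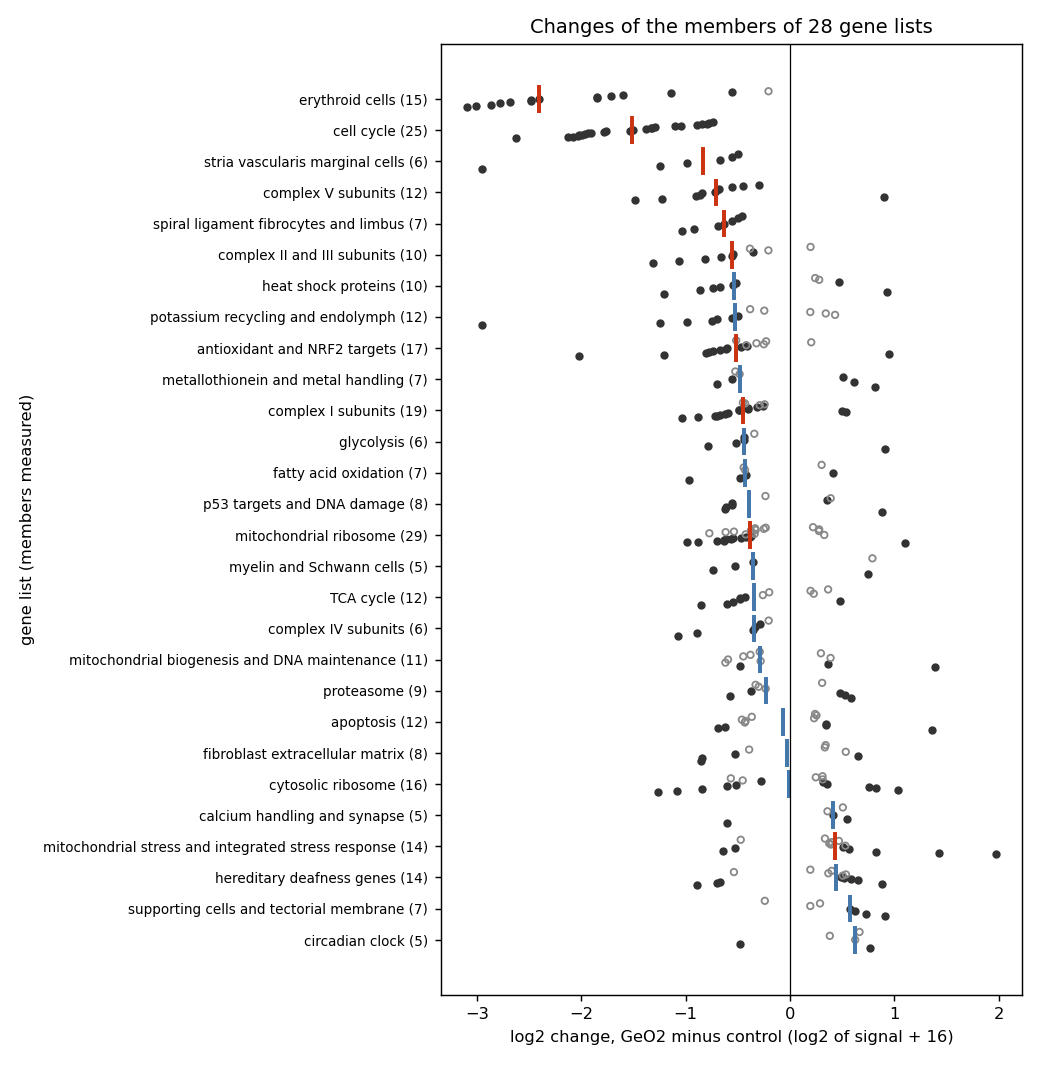
Log2 change, GeO2 minus control (horizontal axis, from log2(signal + 16)), of each measured member of the 28 gene lists tested (vertical axis, with the number of members in brackets). Filled points passed an adjusted p under 0.05, open points did not, and the vertical bar is the list median, red where camera called the list (10 lists) and blue otherwise. The erythroid list has the lowest median, at −2.41, and the stress response list is the called list with a median above 0.

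The other lists tested were not called by camera. Their counts below are over measured members only. Genes listed numbered 14 for heat shock, 50 for deafness, 21 for p53, 29 for apoptosis, 20 for myelin, 52 for the cytosolic ribosome and 28 for the proteasome. They numbered 22 for the fibroblast matrix, 16 for metal handling, 16 for the clock and 18 for calcium handling. Heat shock protein genes had 6 of 10 members that fell, 2 that rose and 2 that did not pass (adjusted p = 0.597), with Hspa1b at −1.21 (SE 0.25), Hsp90aa1 at −0.74 (SE 0.12) and Hspa4 at 0.93 (SE 0.12). Hereditary deafness genes had 5 of 14 that rose, 3 that fell and 6 that did not pass (adjusted p = 0.269), with Wfs1 at 0.89 (SE 0.11) and Myh9 at −0.89 (SE 0.14). Genes of p53 signalling and DNA damage had 4 of 8 that fell, 2 that rose and 2 that did not pass (adjusted p = 0.708). Apoptosis genes had 3 of 12 that rose, 2 that fell and 7 that did not pass (adjusted p = 0.974), and myelin and Schwann cell genes 1 of 5 that rose, 3 that fell and 1 that did not pass (adjusted p = 0.708). Mbp, a myelin gene, fell at its brightest probe set (−0.73) and rose at another (0.95). Cytosolic ribosome genes had 5 of 16 that rose, 6 that fell and 5 that did not pass (adjusted p = 0.983), and the proteasome 3 of 9 that rose, 2 that fell and 4 that did not pass (adjusted p = 0.974). Genes of the fibroblast matrix (1 of 8 rose, 3 fell, 4 did not pass), metal handling (3 of 7 rose, 2 fell, 2 did not pass), the circadian clock (1 of 5 rose, 1 fell, 3 did not pass) and calcium handling and the synapse (2 of 5 rose, 1 fell, 2 did not pass) gave adjusted p-values of 0.825, 0.985, 0.334 and 0.361. Whichever single array was left out, 6 of 8 changes passed for heat shock, 4 of 8 for deafness genes, 3 of 6 for p53, 1 of 5 for apoptosis, 3 of 4 for myelin, 7 of 11 for the cytosolic ribosome, 4 of 5 for the proteasome, 2 of 4 for the fibroblast matrix, 2 of 5 for metal handling, 1 of 2 for the clock and 1 of 3 for calcium handling. With an estimated correlation, camera called 0 of the 28 lists, with 2 at an unadjusted p under 0.05. With the preset correlation it called 10, with 12 at an unadjusted p under 0.05, and fry called 20.

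Lists with under 5 measured members were not tested. Measured means named in the authors' deposited table and tested, so a low number does not show that the array lacks the other members. The hair cell list, for example, holds 22 genes. Neutrophil and marrow myeloid markers had 2 members measured and both rose, Lcn2 and Cd177 (1.95, SE 0.58), Cd177 losing its call when any of 9 single arrays was left out (adjusted p up to 0.0897). The single measured marker of macrophages, Ctss (cathepsin S), rose by 1.22 (SE 0.29), and that of T and NK cells, Il7r, by 1.55 (SE 0.39). Ebf1, the single B cell marker measured, fell at its brightest probe set by 0.71 (SE 0.14), while its others were at −0.45 and 0.40 and did not pass. Interferon response genes (4 measured) had 1 that rose and 3 that fell, inflammation and cytokine genes (3 measured) had 2 that rose and 1 that fell, and immediate early genes (4 measured) had 1 of each and 2 that did not pass. Spiral ganglion neuron genes (3 measured) had 1 that fell, strial basal cell genes (3 measured) had 1 that rose, and the 1 hair cell gene measured, Myo6, rose by 0.65 (SE 0.19), its call lost when any of 6 single arrays was left out (adjusted p up to 0.0858). For bone, 1 of 4 genes rose and 1 fell. For osteoclasts, 1 of 4 rose. For cartilage, 2 of 3 rose and 1 fell. For endothelium and pericytes, 1 of 3 rose and 1 fell. For the central nervous system, 2 of 4 rose and 2 fell. Most of these changes did not pass whichever single array was left out: Ifi35 alone did so among the interferon genes, Lcn2 alone among the inflammation genes, and none for neurons, basal cells or endothelium and pericytes. In bone and cartilage the fall did and the rises did not, in the central nervous system 1 fall did and no rise, and for immediate early genes and osteoclasts every change did. The single skeletal muscle gene measured, of 27 listed, did not pass, and 0 of 12 listed adipocyte genes were measured.

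**Figure D4:**
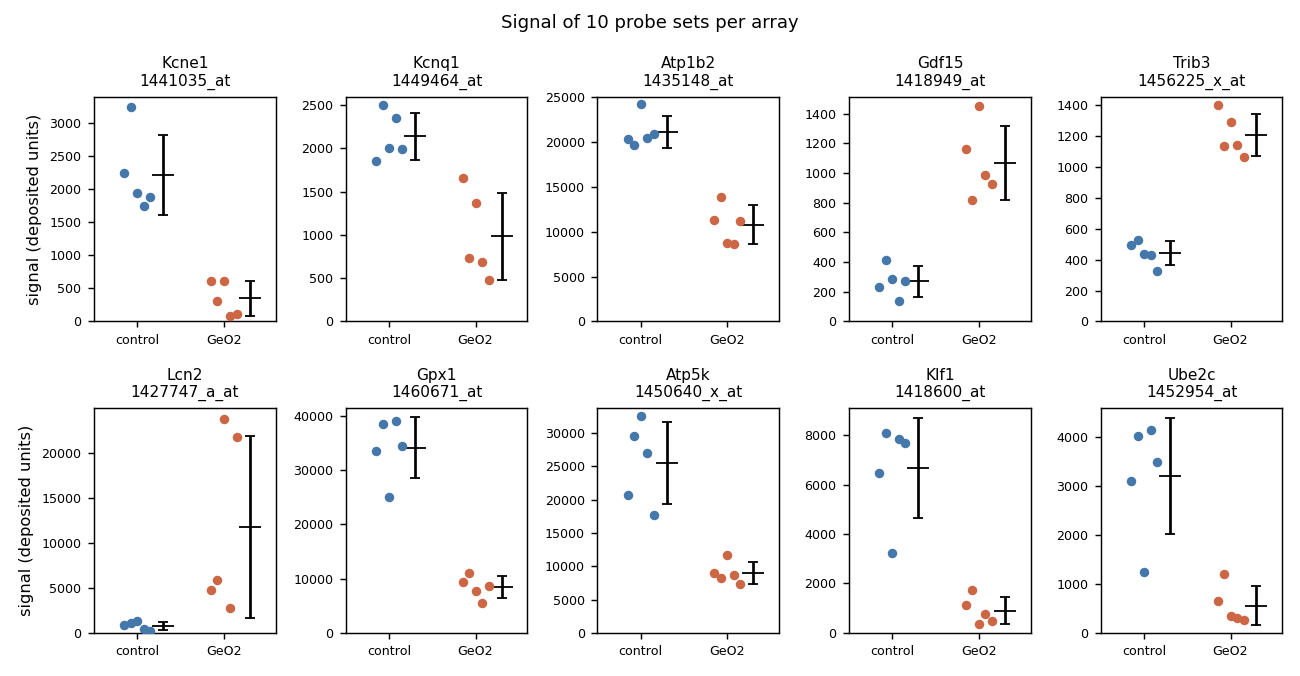
Deposited signal (vertical axes, linear units from 0) of 10 probe sets in control and GeO2. Points are arrays and the bar beside them gives the mean and SD of 5 arrays. Kcne1, Kcnq1, Atp1b2, Gpx1, Atp5k, Klf1 and Ube2c were lower and Gdf15, Trib3 and Lcn2 higher in all 5 GeO2 arrays than in all 5 control arrays, and Lcn2 had an SD of 10146 units in GeO2.

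The series describes its analysis as each GeO2 array set against each control array, 25 comparisons in all. In 3289 of the 27022 probe sets (12.2%) all 25 comparisons went 1 way, with 1770 higher and 1519 lower in GeO2. Chance orderings of 10 arrays give 0.79%, or 214 probe sets. Kcne1, Kcnq1, Atp1b2, Gpx1, Gdf15 and Trib3 were among those separated, and 2838 probe sets were both separated and past the limma threshold. The exact rank-sum test on the same orderings cannot give a p below 0.0079, which Benjamini-Hochberg adjustment turned into 0.0652, so 0 probe sets passed it, with 6447 at an unadjusted p under 0.05 against 8409 for limma.

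Gene Ontology biological process categories, taken from the authors' deposited table, were compared among its genes, since those are the genes with names. Among falling genes, DNA replication stood out, with 32 of 43 genes (74.4%) against 834 of 2689 (31%) in the background (one-sided Fisher's exact test, adjusted p = 5.2e-07 over 115 categories). Mitosis, with 22 of 40 falling genes (55%), did not pass (adjusted p = 0.0742). Over all changed genes, 0 categories passed in Fisher's exact test, with 12 at an unadjusted p under 0.05, and the 4 with the lowest adjusted p (0.0844) were mitosis, cytokinesis, nucleosome assembly and DNA replication. Among rising genes, 0 categories passed, with 8 at an unadjusted p under 0.05, and the lowest adjusted p was 0.229, shared by DNA-dependent regulation of transcription, protein amino acid phosphorylation, cell adhesion and transcription. The erythroid score was lower in the same GeO2 arrays, and its relation within groups was computed for the cell cycle list but not for these categories.

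The authors' deposited table holds 7806 probe sets, 3979 higher and 3827 lower in GeO2, at an unadjusted p under 0.05 and a fold of at least 1.2. Of the 7178 that were also tested here, 4285 (59.7%) passed the adjusted threshold, and all 7178 had the same direction. Both come from the same arrays, so the overlap is not an independent check. Among genes with several changed probe sets, 65 of 569 (11.4%) had probe sets in both directions, Mbp and Hadhb among them. Directions given for a gene refer to its brightest probe set among those tested and named in the authors' deposited table. For the largest rises and falls they refer to the brightest of these that passed and were separated in all comparisons. A gene's brighter probe sets outside that table, if any, are unnamed and were not read, so a direction may not hold for the whole gene.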

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

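The test that sets Kcne1 against Kcnq1, the erythroid score as a covariate and the slope test of the respiratory chain were chosen only after the data or the result had been seen. In groups of 5 arrays, 22 values stood apart from the other 4 of their group by Dixon's criterion, out of 432 groups tested, and chance alone gives about 22, so their number is no more than chance. Values below are log2(signal + 16).

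Control replicate 3 had low values for Klf1 (11.67, the nearest other control array at 12.66), Ube2c (10.29 against 11.61), Ccnb2 (10.1 against 11.24), Rsad2 (13.86 against 14.73) and the erythroid score (12.22 against 13.05). Control replicate 2 stood apart for Mrpl34 (11.65, nearest 11.1), Fis1 (11.27, nearest 11.61), Plk2 (10.79, nearest 11.28), Otog (13.29, nearest 12.59) and the interferon response score (12.56, nearest 12.19). Control replicate 4 did so for 8430436C05Rik (9.68, nearest 9.16), Hspa1b (12.15, nearest 13.15) and the tricarboxylic acid cycle score (13.81, nearest 13.56), and control replicate 5 for the potassium recycling score (11.93, nearest 12.04). In GeO2, replicate 3 stood apart for Cox6b1 (15.13, nearest 15.02), Cpt1b (10, nearest 9.11) and Slc39a8 (12.84, nearest 12.34). GeO2 replicate 2 did so for Cytl1 (10.26, nearest 10.97), Tfrc (14.09, nearest 13.85) and the glycolysis score (13.15, nearest 12.83). GeO2 replicate 4 was high for Gmfb (10.01, nearest 9.15) and GeO2 replicate 5 low for Hsp90aa1 (13.55, nearest 13.92).

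The 4408 changed probe sets were set against other splits of the 10 arrays into groups of 5. Of 100 splits drawn, the real one included, 1 gave as many, the real one, and the highest of the others gave 218. The spread between these arrays is therefore argued against as the source of this count. Splits of arrays cannot exclude a chance difference between pools, if the samples are not single animals. They also cannot exclude a difference in dissection or handling between the groups.

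The first pattern weighed is the fall of all 25 measured cell cycle genes. Uneven scaling between arrays is argued against, because the median log2 value of an array ran only from 10.308 to 10.389. Under quantile normalization the list median kept 92.9% of its size. With array medians so close, that normalization could hardly have moved a list median, so the percent kept, here and below, adds little. Neither value can show a difference in total RNA between the groups. Loss of erythroid precursors, which divide, is a candidate explanation that the tests leave standing: within groups the list tracked the erythroid score (r of 0.91, permutation p = 0.00111), and with that score as a covariate the median went from −1.52 to −0.26, with 25 members passing before and 0 after. The median standard error was 0.31 before and 0.33 after, so the calls ended because the differences shrank. Whether GeO2 lowered such cells in the temporal bone or the dissections carried less marrow or blood stays open: less marrow would lower its myeloid markers too, and the 2 measured rose (Lcn2 by 3.60 and Cd177 by 1.95, the latter not in every omission of 1 array), but 2 genes, which can also be induced by inflammation, do not decide it, and no measure of dissection was used here.

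The next pattern is the fall of 36 of 47 measured respiratory chain genes. Uneven scaling is argued against by the same close array medians, with 100.4% of the list median kept under quantile normalization. Loss of erythroid precursors, which are rich in mitochondria, is argued against by the correlation within groups, which was −0.34 (permutation p = 0.409; rho of −0.22, p = 0.562; r of 0.10 without the 2 farthest arrays) where the explanation needs a clearly positive one. The slope of the respiratory chain score on the erythroid score within groups was −0.06 (SE 0.06), 5.13 standard errors below the 0.26 that would account for the group difference. That slope was not recomputed without the 2 farthest arrays, so its distance in standard errors may rest on few arrays. The comparison also assumes a straight line between these log2 scores over both groups. A flatter relation at the low erythroid scores of GeO2 would shorten that distance. The correlation and slope therefore argue against this explanation without excluding it. With that score as a covariate the median was −0.62 against −0.55 without it. Passing members went from 39 to 0 because the median standard error rose from 0.11 to 0.21. A smaller share of strial marginal cells or spiral ligament fibrocytes, whose markers fell in the same arrays, was not tested as an explanation and stays open. An effect of GeO2 on these transcripts remains a hypothesis, found and tested on the same arrays.

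The last pattern is the fall of all 6 strial marginal cell markers. Uneven scaling is argued against by the same close array medians, with 98.6% of the list median kept under quantile normalization. The log2 change of Kcne1 minus that of Kcnq1, both markers of these cells, was −1.71 (SE 0.34). A smaller share of marginal cells and a change of transcription within them cannot be told apart by that value, because Kcne1 was set against Kcnq1 after its large fall had been seen, and because Kcnq1 signal from other cells or from probe background could narrow its own fall. Both stay open.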

How the results depend on the processing

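The erythroid covariate and the pooled-variance test on linear signals were alternatives chosen only after seeing the data. The 4408 changed probe sets became 2623 with a minimum fold of 1.5, 0 by the exact rank-sum test (6447 at an unadjusted p under 0.05; 3290 probe sets reached its smallest possible p, 0.0079, and 4290 would have had to for any to pass) and 4 with the erythroid score as a covariate (3316 at an unadjusted p under 0.05), whose tie to the group inflates standard errors 1.92-fold at equal residual spread. Leaving out single arrays gave 2794 (without GeO2 replicate 5) to 4854 changed probe sets (without GeO2 replicate 1), 3565 to 4719 separated in all pairwise comparisons, and 9 to 11 called lists. The fit with the replicate number as a block gave 4431 probe sets and 9 lists. Same-numbered arrays correlated at −0.05 to 0.17 and none was the best partner of its number both ways. No clear pairing by number was seen, but this check cannot exclude a weak one. Over the remaining alternatives the count ran from 3244 (pooled-variance test, linear signals) to 6447 (adjusted p under 0.10), with 4486 under quantile normalization and 6197 with array weights. The 10 called lists became 0 with estimated correlations and 20 with fry; quantile normalization gave 11 lists and the shift to 1 median 10, all 10 kept in both, and the erythroid covariate 8, of which 7 were among the 10. With that covariate the cell cycle, erythroid and stress response lists lost their calls, the erythroid one because the covariate is its own score. Gene Ontology categories numbered 0 over all changed genes and 1 with rising and falling genes tested separately, and the overlap with the authors' deposited table went from 4285 to 6861 at an unadjusted p under 0.05. Of the 154 named probe sets that passed, 99 passed whichever array was left out, 4 lost their call under quantile normalization (Dguok, Plk2, Hspa8 and Otog) and 0 did with an offset of 64 in limma; no direction was reversed. The planned covariate for RNA quality was not run, since it needs control probe sets, which were not analysed here. Signal over background per probe set is not given in the sources used here, so dim probe sets are limited by the offset and filter alone. The cause was not tested where not stated.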

Other observations

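The genes of this part, and the comparisons between them, were chosen only after their values were seen. Several single genes known from immune cells were higher in GeO2, unevenly between arrays, and were not tested as a group. Sets fixed without regard to these values were mixed. The 2 measured neutrophil and marrow myeloid markers rose, as did the single measured markers of macrophages and of T and NK cells. The single measured B cell marker fell. Of 4 measured interferon genes 3 fell and 1 rose, and of 3 inflammation genes 2 rose and 1 fell. Among rising genes, the immune response category held 6 of 21 (28.6%) and the inflammatory response 3 of 13 (23.1%), against 29.7% in the background. Chemotaxis held 10 of 18 (55.6%), which did not pass (one-sided Fisher's exact test, adjusted p = 0.439). All 4 tested probe sets of immunoglobulin genes named in the authors' deposited table rose. A heavy chain variable region probe set, Igh-VJ558, had a mean signal of 25814 units in GeO2 and 1522 in control (log2 change 3.41, SE 0.72, adjusted p = 0.00787 in limma), another of the same gene rose as well, and 2 that read the kappa light chain rose by 1.61 (SE 0.44) and 1.67 (SE 0.44). In each of these 4, 4 of 5 GeO2 arrays lay above the highest control array. Sftpd, surfactant protein D, a secreted collectin of innate immunity, rose by 2.64 (SE 0.71, adjusted p = 0.0245), with 3 of 5 GeO2 arrays above all controls. Mpeg1, a macrophage perforin, rose by 1.43 (SE 0.36) and the chemokine gene Ccl6 by 1.54 (SE 0.43). Slfn2 was higher in 5 of 5 GeO2 arrays than in all controls. Ebf1, a B lineage factor, was lower at its brightest probe set while the immunoglobulin probe sets were higher. Immunoglobulin probe sets can read several family members, so these values belong to the family and not to 1 gene.

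Of further genes known from red cell precursors, Blvrb and Gata1 were lower too, while Hba-a1 differed between its probe sets. Gata1 and Hba-a1 are members of the erythroid list already described. Blvrb, biliverdin reductase B, changed by −2.48 (SE 0.30) and Gata1 by −2.48 (SE 0.34). Hba-a1 changed by −1.97 (SE 0.39) at 1 probe set, from 26307 to 8247 units, and by −0.21 (SE 0.09, adjusted p = 0.128) at another, from 41438 to 35964 units. Among the 4 probe sets that passed with the erythroid score as a covariate were those of Cox6a1 (−1.56, SE 0.21), Igfbp2 (−1.38, SE 0.19) and Sgsm2 (−4.06, SE 0.55), each at an adjusted p of 0.0483. Without the covariate, that Cox6a1 probe set changed by −1.19 (SE 0.12) and the gene's brighter one by only −0.29 (SE 0.08).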
